A study of Sorghum bicolor with 12 samples.

How the data were processed

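The material was leaf RNA of 2 sorghum (Sorghum bicolor) cultivars, Sanchisan (SCS) and Jinliang 5 (JL), each grown with a normal water supply (control) or under drought. Each of the 4 groups holds 3 libraries, 12 in all. Per the labels, RNA was extracted with TRIzol, its integrity was read on a Bioanalyzer, and strand-specific NEBNext Ultra libraries were run on an Illumina NovaSeq instrument. The length and depth of the drought, the age of the leaves and the origin of the 3 libraries of a group are not given in the labels. Since nothing says that the libraries of a group came from separate plants, the p-values measure only the spread between these samples, which may be technical.

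The submitters' processing notes name HISAT2 2.0.4, STAR and StringTie 1.3.3b with no role or order. The program that assigned reads to genes, its strand setting and the genome build are not given in the sources used here. The values tested were the whole-number counts per gene that the authors deposited, which were not normalised. The gene table holds 33897 genes, of which 946 are loci the authors assembled without a reference gene. Of its genes, 32940 matched the reference gene table of assembly Sorghum_bicolor_NCBIv3 by identifier, and 32939 of those had the same start and end there. Coordinates are printed as the deposited table gives them. Gene names and product descriptions are those of the deposited table. The FPKM values deposited by the authors equalled count divided by gene length and by 1 constant per library, which was 0.758 to 1.41 times the library's total count. What set that constant is not given in the sources used here, and FPKM served only for alternative fits. How reads shared by near-identical gene copies were counted is not given either, so values of single members of close families (group 3 LEA genes, B-type expansins, P5C synthases, ribosomal proteins) are uncertain.

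Library totals ranged from 15.04 to 18.4 M counts. Every pair of libraries within a group differed by more than counting noise, with a chi-square of 42.9 to 301 per gene, so no library was counted as a repeat of another. Genes were kept with edgeR's filterByExpr at its defaults, which left 20873 genes and removed 13024. Counts were scaled with TMM (factors 0.757 to 1.41). The edgeR (4.0.16) quasi-likelihood F test was fitted in R 4.3.3 with 1 mean per group over all 12 libraries, since the groups share 1 estimate of the spread. The biological coefficient of variation was 63.3%. The 5 comparisons were drought against control in SCS, the same in JL, the interaction (the JL change minus the SCS change), and JL minus SCS in control and in drought. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all tested genes, with no fold threshold. CPM in the text are TMM-scaled and given as mean ± SD of 3 libraries, and log2 fold changes carry the standard error (SE) of the fit. A fold against a group with 0 counts is a lower bound, computed against a floor of 3 counts over the group. A group with 1 to 3 counts gives a ratio with its exact 95% binomial interval. Floors and intervals cover counting error only. Such folds were also computed without each library of the higher group, a check added after their values were seen. Fitted log2 fold changes of such genes depend on the prior count.

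Gene lists were fixed as search patterns on product descriptions, and 47 lists were tested. Before any list test, 10 lists were corrected for false matches and 1 that matched plant proteins only was dropped. Lists were tested with limma (3.58.1) camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. Camera compares a list with all other genes, and fry, run beside it, tests whether the genes of a list move on balance in 1 direction. No camera call in any comparison held with a correlation estimated per list. In total 37 of the 2976 tested list genes belong to more than 1 list. The groups, the tests, the alternatives, the lists and the rule for named genes were set before the data were examined. The rule took, per comparison, up to 10 genes with the highest and 10 with the lowest log2 fold change among called genes with a known product, a mean of at least 10 CPM in the higher group and, between 2 groups, no overlap of libraries. It added up to 3 members of each list called by camera for the drought comparisons and the interaction, and the expressed genes of proline and dhurrin metabolism in both drought comparisons. Of the last, all 9 genes of the proline list are named for SCS, and otherwise the first 5 of each list in the order of the deposited table. For the interaction 7 genes of each ranking are named, and a sterol methyltransferase caught by the ethylene pattern was skipped. These limits on the names were set after values had been seen.

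Alternatives were DESeq2 1.42.0, RLE and upper-quartile scaling, no filter and a stricter filter, fits of the compared libraries alone, a replicate block, fold thresholds, limma-trend on log2(FPKM + pseudocount) and leaving out each library in turn. Added after seeing the data were a fit without the drought libraries numbered 2, 1 surrogate variable (sva 3.50.0) and voom with library quality weights. Simulated counts used each gene's mean over the 12 libraries and 1 dispersion per gene for all groups, with genes independent of each other. The 200 changed genes had a mean of at least 10 CPM. Real groups differ in spread and their genes vary together, so recovery in the real data may be lower. On the simulated counts edgeR made 2 to 4 false calls per comparison. Of 50 genes changed by 8-fold it recovered 68% for drought in SCS, 62% for drought in JL, 28% for the interaction, 62% between cultivars in control and 68% in drought. For 4-fold these shares were 28%, 28%, 12%, 36% and 22%, and for 2-fold 2%, 2%, 0%, 0% and 0%. DESeq2 made 94 false calls beside 131 recovered genes of 200 in the simulation for SCS, and 97 beside 131 in that for JL. There edgeR recovered 90 and 85, so both its higher recovery and its false calls bear on DESeq2's larger counts. Limma on log2 values made 9 and 7 false calls. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.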

Results

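Leaf transcriptomes were measured in 2 sorghum cultivars under a normal water supply and under drought, in 4 groups of 3 libraries. Mean totals were 17.9 ± 0.497 M counts in SCS control, 15.8 ± 0.257 in SCS drought, 15.7 ± 0.251 in JL control and 15.5 ± 0.464 in JL drought (SD, n = 3). The 100 most abundant genes took more of the counts in JL (37.2 ± 5.24% in control and 35.7 ± 3.43% in drought) than in SCS (23.5 ± 5.43% and 19.0 ± 3.51%). The first principal component of log2 CPM held 35.5% of the variance and set the SCS drought libraries (scores of 136 to 191) apart from the other 9 (-110 to 4.17). Libraries of 1 group also differed: the median SD of a gene within a group was 0.41 on the log2 scale in SCS control, 0.58 in SCS drought, 0.43 in JL control and 0.66 in JL drought. The leading direction of these differences held 39.5% of the variation within groups and ran highest in replicate 2 of both drought groups (scores of 0.42 in SCS and 0.44 in JL) and lowest in JL drought 1 (-0.49) and SCS drought 3 (-0.39). Genes of photosystems and of chlorophyll synthesis varied along it within groups, with a median gene correlation of 0.591 and 0.684 over the 12 libraries.

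**Figure D1:**
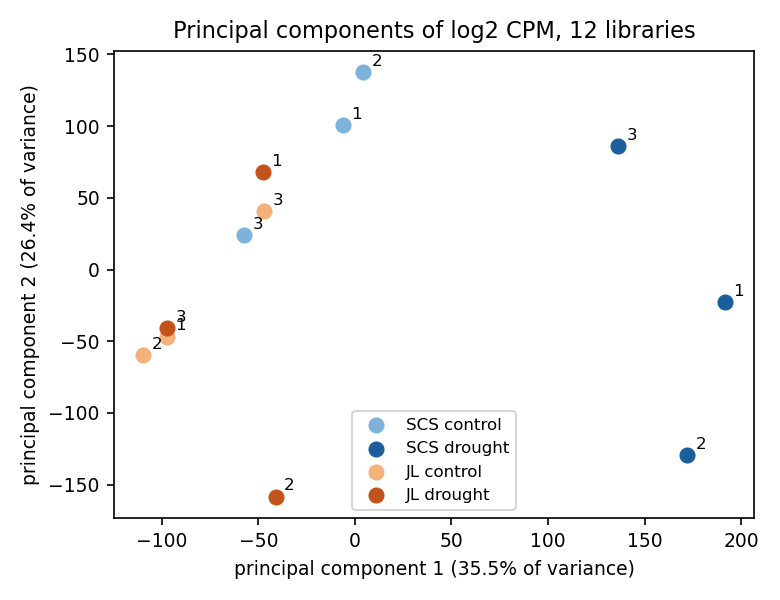
Scores of the 12 libraries on principal components 1 and 2 of log2 CPM (35.5% and 26.4% of the variance), each point a library coloured by group and numbered by replicate. The 3 SCS drought libraries lie at 136 to 191 on component 1 and the other 9 at -110 to 4.17, and component 2 spreads the libraries within groups.

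The first question was how SCS leaves responded to drought. LEA proteins are hydrophilic proteins that accumulate in maturing seeds and drying tissue, and of 22 LEA and dehydrin genes 15 rose and 1 fell. By camera the lists of LEA proteins, lipid-transfer proteins and raffinose and trehalose synthesis stood higher, and those of the photosystems, the C4 and Calvin cycle enzymes and plastid ribosomes lower. None of these calls held with an estimated correlation (adjusted p of 0.313 or more). Of 9 proline genes 4 rose, among them 1 of breakdown. Dehydrin DHN1 (LOC8077913, chromosome 9, 45915591 to 45916640) rose from 0.329 ± 0.249 CPM in control to 5566 ± 3821 CPM in drought (SD, n = 3), a log2 fold change of 14.04 (SE 2.66, adjusted p = 0.0122). In all, 1984 of 20873 genes were called, 854 higher and 1130 lower in drought, and 1892 of these changed by 2-fold or more. The balance of directions depends on the fit: it was 970 higher and 756 lower with the compared libraries alone, 1313 and 1306 without SCS drought 3 and 227 and 581 without SCS control 1. In 33.8% of tested genes the libraries of the 2 groups did not overlap, against the 10% expected per gene by chance for 3 against 3. Genes vary together, so here and in the later comparisons such a share can stray from 10% by chance. How far was not computed.

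Of the 10 named genes with the largest increases, 9 had no count in the control libraries. A group 3 LEA gene (LOC110430243, chromosome 9, 56036770 to 56038025) reached 2034 ± 1461 CPM, at least 40923-fold higher (adjusted p = 0.00332). LOC8065192, named for a low-temperature-induced protein known in Arabidopsis as an ABA-responsive gene, reached 907 ± 599 CPM, at least 18336-fold higher (adjusted p = 0.00381). The sugar exporter gene SWEET15 (LOC8056792) reached 709 ± 447 CPM and CS66 (LOC8071330), a dehydrin named after a wheat cold-induced protein, 685 ± 592 CPM. These were at least 14394-fold and at least 13665-fold higher (adjusted p = 0.0222 and 0.0448). A pore protein of the plastid outer envelope (LOC110434017) was at least 5418-fold higher, at 270 ± 202 CPM. Laccase-13 (LOC8058891), of a family that polymerises lignin, was at least 3787-fold higher at 184 ± 210 CPM, and its bound became 1272-fold without SCS drought 2 and 5868-fold without SCS drought 3. The small LEA gene LOC8073244 and the group 3 genes LOC8072323 and LOC110434031 were at least 2114-fold, 1935-fold and 1017-fold higher. Without SCS drought 1 the bounds of LOC110430243, LOC110434017, LOC8073244 and LOC8072323 became 26789-fold, 3531-fold, 1193-fold and 950-fold, and without SCS drought 3 that of CS66 21864-fold.

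Of the 10 named genes with the largest decreases, 2 had no count in the drought libraries. A high-affinity nitrate transporter gene (LOC8078590) fell from 12.4 ± 6.61 CPM to 0 counts in drought, at least 239-fold lower (adjusted p = 0.00866), and the lipid-domain gene LOC8063647 was at least 575-fold lower (adjusted p = 0.0394), or 318-fold without SCS control 3. LOC110433327, of the NRT1/PTR family of nitrate and peptide transporters (chromosome 3, 70388656 to 70393648), went from 31.1 ± 14.4 CPM to 2 counts over the group, a control to drought ratio of 917 (254 to 7580) (adjusted p = 0.00139). HEADING DATE 3A (LOC8075576), the florigen gene of rice by name, went from 17.7 ± 8.04 CPM to 1 count, a ratio of 1025 (184 to 40525) (adjusted p = 0.0204). Gibberellin 20 oxidase 2 (LOC8063144), an enzyme of gibberellin synthesis, fell from 46.2 ± 32.3 to 0.0944 ± 0.0712 CPM (log2 fold change -8.78), and the phosphate exporter gene PHO1-3 (LOC8072930) from 22.01 ± 16.99 to 0.0801 ± 0.0763 CPM (-7.94). The senescence-specific cysteine protease gene SAG39 (LOC8086230) fell from 138 ± 134 to 0.486 ± 0.349 CPM, the aspartic proteinase nepenthesin-1 (LOC8074284) from 141 ± 35.8 to 0.450 ± 0.517 CPM. The oxidoreductase gene LOC8083891 fell from 33.4 ± 17.2 to 0.0675 ± 0.117 CPM and the PHD finger gene LOC8075860 from 140 ± 113 to 0.482 ± 0.297 CPM. Their log2 fold changes were -8.14, -8.23, -8.81 and -8.15.

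Of the fixed lists, 5 stood higher and 5 lower than other genes by camera. Among 22 LEA and dehydrin genes, 15 rose and 1 fell (18 and 2 adjusted over the list alone), with a median log2 fold change of 8.17 that was the same with genes at 0 set to their bound. The list's adjusted p was 5.05e-16 by camera, 0.313 with an estimated correlation and 2.04e-04 by fry. LEA protein 1 (LOC8055903, chromosome 1, 67521488 to 67523058) rose from 0.874 ± 0.218 to 246 ± 135 CPM (8.12, SE 0.867, adjusted p = 0.00267). Of 23 genes of non-specific lipid-transfer proteins, which carry lipids towards the cuticle among other roles, 12 rose and 0 fell (15 and 2 adjusted over the list alone). Their median was 4.39, also at the bound, with an adjusted p of 1.52e-07 by camera, 0.313 with an estimated correlation and 0.00224 by fry. LOC8061116 rose from 0.0985 ± 0.0883 to 105 ± 45.9 CPM, LOC8074864 from 17.1 ± 6.29 to 438 ± 310 CPM and LOC8080746 from 7.58 ± 1.83 to 42.2 ± 14.03 CPM. Of 27 raffinose and trehalose genes, 6 rose and 1 fell (9 and 2 adjusted over the list alone; median 1.51). The adjusted p was 2.53e-04 by camera, 0.515 with an estimated correlation and 0.0335 by fry. The raffinose synthase gene LOC8078430 (galactinol-sucrose galactosyltransferase, chromosome 2, 7874433 to 7877967) rose from 150 ± 26.3 to 6897 ± 4862 CPM (5.52, SE 0.75), its relative LOC8057100 from 36.7 ± 6.46 to 990 ± 609 CPM. The trehalose-phosphate synthase gene LOC8069829 rose from 30.6 ± 5.26 to 66.5 ± 10.6 CPM. Of 107 ethylene synthesis and response genes, 12 rose and 2 fell (16 and 2 adjusted over the list alone; median 0.85). The list had an adjusted p of 0.00175 by camera, 0.445 with an estimated correlation and 0.0433 by fry. Without 5 products matched through the word methylene, 11 of 102 rose and 2 fell (15 and 2 adjusted over the list alone; median 0.88), with an adjusted p of 0.00191 by camera, 0.509 with an estimated correlation and 0.0489 by fry. The ethylene-signalling factor gene LOC8078580 (ETHYLENE INSENSITIVE 3-like) rose from 8.38 ± 3.61 to 32.2 ± 4.33 CPM, and the response factor gene LOC8076148 from 5.27 ± 1.35 to 53.4 ± 17.8 CPM. Of 204 cytosolic ribosomal protein genes 3 rose and 0 fell, none when adjusted over the list alone, and the median was 0.16 (adjusted p = 0.00482 by camera, 0.850 with an estimated correlation, 0.601 by fry). The called members included LOC8082350 (an L10 protein), at 4.26 ± 1.85 and 194 ± 184 CPM, and the L18a-like gene LOC110434018, at 9.59 ± 0.886 and 40.97 ± 11.4 CPM.

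Of 81 photosystem and light-harvesting genes, 0 rose and 30 fell in SCS drought (0 and 46 adjusted over the list alone), with a median log2 fold change of -1.74. The adjusted p was 2.68e-14 by camera, 0.592 with an estimated correlation and 0.0208 by fry. The photosystem II 5 kDa protein gene (LOC8070565, chromosome 4, 54521138 to 54521839) fell from 552 ± 253 to 54.2 ± 11.5 CPM (-3.35, SE 0.474, adjusted p = 0.00465), the NDH subunit gene LOC8073405 from 498 ± 163 to 101 ± 32.2 CPM. The photosystem II assembly gene LOC8081314 fell from 112 ± 28.04 to 26.8 ± 6.85 CPM. Of 48 genes of C4 photosynthesis and the Calvin cycle, 3 rose and 15 fell (3 and 19 adjusted over the list alone; median -0.78), with an adjusted p of 0.0132 by camera, 0.686 with an estimated correlation and 0.0208 by fry. The plastid glyceraldehyde-3-phosphate dehydrogenase gene LOC110436299 fell from 2209 ± 1259 to 176 ± 34.6 CPM (-3.65). The phosphoribulokinase gene LOC110434320, of the step that renews the carbon dioxide acceptor, fell from 1532 ± 886 to 183 ± 42.04 CPM (-3.06). The plastid NADP-malic enzyme gene LOC8065884 fell from 103 ± 4.36 to 11.1 ± 6.50 CPM. Marker lists of leaf cell types were called lower by fry: of 14 bundle sheath markers 2 rose and 5 fell (adjusted p = 0.0386 by fry, 0.0889 by camera and 0.686 with an estimated correlation), and of 22 mesophyll markers 1 rose and 6 fell (0.0180, 0.184 and 0.715). Of 59 plastid ribosomal protein genes, 0 rose and 7 fell (1 and 23 adjusted over the list alone; median -1.32), with an adjusted p of 2.44e-07 by camera, 0.646 with an estimated correlation and 0.0281 by fry. The L31 gene LOC8054924 fell from 162 ± 45.5 to 33.6 ± 12.8 CPM, the S21 gene LOC8079435 from 157 ± 46.7 to 26.1 ± 3.21 CPM and the L35 gene LOC8069333 from 149 ± 37.5 to 27.6 ± 2.43 CPM. Of 29 chlorophyll synthesis genes 3 fell and 0 rose, likewise 3 and 0 adjusted over the list alone (median -0.85; adjusted p = 0.0187 by camera, 0.808 with an estimated correlation and 0.204 by fry). The glutamyl-tRNA reductase gene LOC8079551, of the first committed step towards chlorophyll, fell from 944 ± 532 to 55.7 ± 37.9 CPM. LOC8077402 (chlorophyllide a oxygenase, which makes chlorophyll b) fell from 330 ± 169 to 112 ± 8.98 CPM and the reductase-binding gene LOC8073256 from 18.9 ± 0.308 to 8.34 ± 2.17 CPM. Of 558 receptor-like kinase and NB-LRR genes, the families of surface and intracellular immune receptors, 13 rose and 37 fell (12 and 32 adjusted over the list alone; median -0.65, or -0.64 with genes at 0 set to their bound). The list's adjusted p was 0.0283 by camera, 0.776 with an estimated correlation and 0.102 by fry. The kinase genes LOC8073249, LOC8084167 and LOC8074343 fell from 17.1 ± 6.83, 192 ± 81.5 and 98.8 ± 9.64 to 0.888 ± 0.394, 6.68 ± 3.23 and 25.3 ± 6.005 CPM.

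Proline is an osmolyte of drying plant cells. Of 9 genes of its metabolism and transport, 4 rose and 1 fell in SCS (5 and 1 adjusted over the list alone; median 2.22), with an adjusted p of 0.0732 by camera, 0.592 with an estimated correlation and 0.0435 by fry. P5C synthase makes the precursor of proline. Its gene LOC110430201 (chromosome 9, 51780110 to 51787205) rose from 24.6 ± 10.1 to 404 ± 252 CPM (4.04, SE 0.681, adjusted p = 0.00817). The 2 other P5C synthase genes were not called: LOC110433516 stood at 365 ± 49.95 and 1856 ± 846 CPM (adjusted p = 0.0596) and LOC8072535 at 13.6 ± 7.91 and 9.29 ± 4.20 CPM (0.674). The P5C reductase gene LOC8081331, of the step from that precursor to proline, rose from 1.97 ± 0.801 to 25.2 ± 9.90 CPM (3.67, adjusted p = 0.0213). P5C dehydrogenase (LOC8068986), an enzyme of proline breakdown, rose from 19.5 ± 5.83 to 128 ± 13.5 CPM (2.71, adjusted p = 0.0114), and proline dehydrogenase 2 (LOC8058116), also of breakdown, stood at 75.4 ± 14.6 and 31.6 ± 30.8 CPM (0.515). Ornithine aminotransferase (LOC8062211), which leads to the same precursor, rose from 38.2 ± 6.27 to 178 ± 22.5 CPM (adjusted p = 0.0037), while proline transporter 1 (LOC8078705) fell from 86.6 ± 50.7 to 1.56 ± 1.22 CPM (-5.78, adjusted p = 0.00321). Proline transporter 2 (LOC8081574) stood at 103 ± 12.8 and 109 ± 56.4 CPM (adjusted p = 0.925). Dhurrin is the cyanogenic glucoside of sorghum. Of 11 genes of its synthesis and breakdown 1 rose and 0 fell, with the same counts adjusted over the list alone (adjusted p = 0.548 by camera and 0.667 by fry). The glucosyltransferase gene LOC8060874, of the last step of synthesis, rose from 1.91 ± 0.408 to 127 ± 102 CPM (adjusted p = 0.0278). The lyase gene LOC110435085, of the step that frees hydrogen cyanide, stood at 86.8 ± 41.05 and 472 ± 380 CPM (adjusted p = 0.099), and a relative, LOC110435343, at 14.01 ± 3.94 and 8.01 ± 4.88 CPM (0.43). The oxime monooxygenase genes LOC8060873 and LOC8060872 stood at 11.4 ± 3.86 and 62.3 ± 80.3 in control and 31.1 ± 29.7 and 26.4 ± 45.8 CPM in drought (0.405 and 0.748).

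The 1984 calls of SCS changed in number without 1 library: 808, 1043 and 533 genes were called without SCS control 1, 2 and 3, and 617, 1207 and 2619 without SCS drought 1, 2 and 3. Such fits have fewer libraries, and lost power was not separated from dependence on a given library. DESeq2 called 4065 genes. Camera's 10 lists were matched or passed by other splits of the same libraries, which gave up to 17 lists by camera but none by fry, against 15 for the real split. Those splits mix control and drought libraries, so the drought change widens their spread, and the lack of fry calls says little about its errors. Among the 52 named genes called in SCS, 33 kept the call without any 1 library. The calls lost were 12, 8 and 14 without SCS control 1, 2 and 3 and 15, 8 and 3 without SCS drought 1, 2 and 3. SWEET15 (LOC8056792) lost its call in 4 of the 6 fits, CS66 (LOC8071330), HEADING DATE 3A (LOC8075576), LOC8060874, LOC8077402, LOC8073256, LOC8069333 and LOC8081331 in 5 and LOC8063647 in 6. Dehydrin DHN1 (LOC8077913) lost it without SCS control 1 or 3 (adjusted p up to 0.0639), LOC8082350 in 3 fits, LOC8076148 and LOC110434018 in 2, and LOC8063144, LOC8069829, LOC8074864, LOC8078580, LOC8079551 and LOC8080746 in 1. By camera, the C4 and Calvin cycle list and the chlorophyll synthesis list lost their calls without SCS control 3 or SCS drought 3 (adjusted p up to 0.088 and 0.12), the cytosolic ribosomal list without SCS control 3 (0.428). The receptor list lost its call without SCS control 1, SCS control 2 or SCS drought 1 (up to 0.206). The other 6 lists kept theirs.

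**Figure D2:**
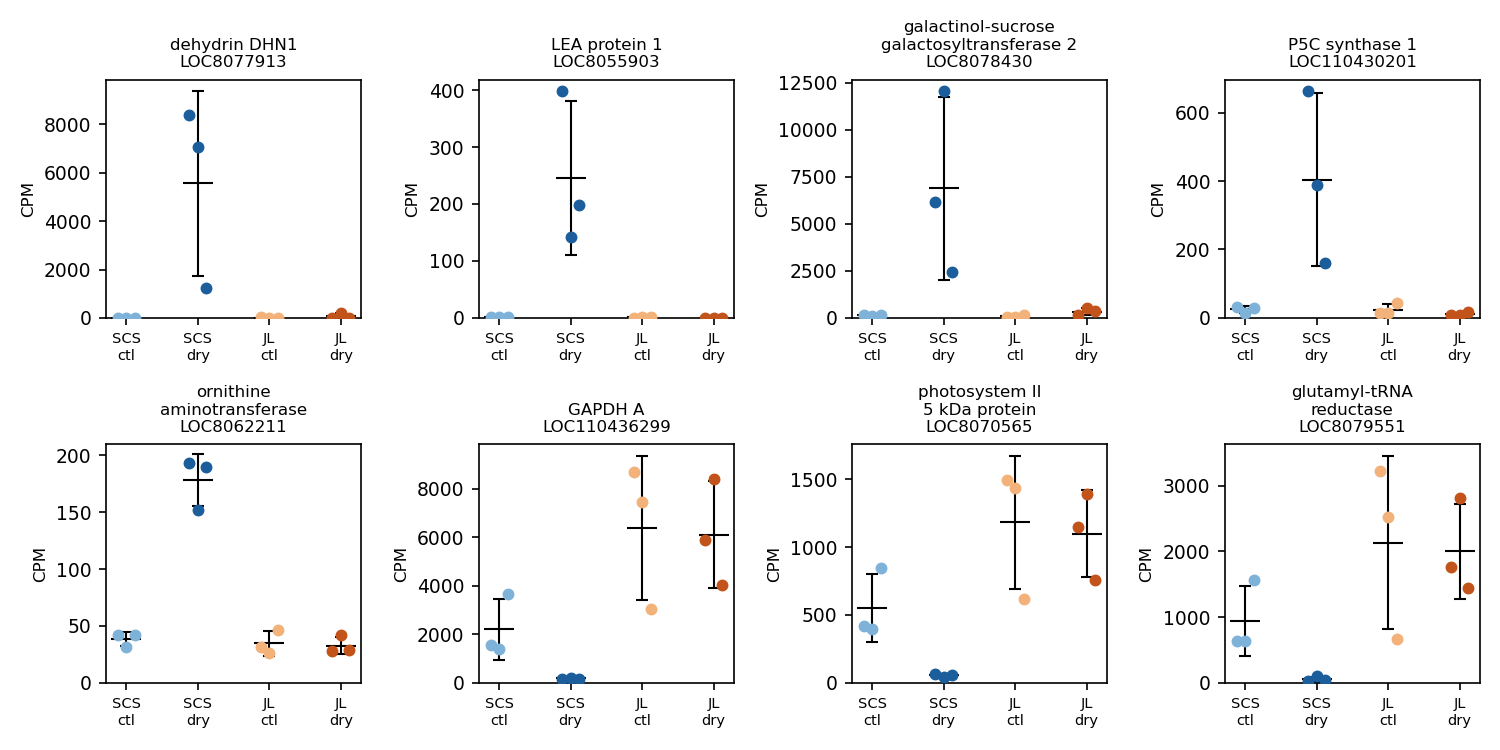
TMM-scaled CPM of 8 genes in the 4 groups (ctl, control; dry, drought), with points for libraries and black bars for the mean ± SD of 3 libraries, the lower bar ended at 0. In SCS drought 5 of them (dehydrin DHN1, LEA protein 1, a galactinol-sucrose galactosyltransferase, P5C synthase 1 and ornithine aminotransferase) stand above SCS control and 3 (GAPDH A, a photosystem II protein and glutamyl-tRNA reductase) below, and no gene was called for drought in JL.

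In JL leaves, no gene was called for drought against control by edgeR. On simulated counts it recovered 2% of genes changed by 2-fold in JL drought, 28% at 4-fold and 62% at 8-fold. Those counts gave all groups the same spread, while JL drought had the largest median SD within a group (0.66). Recovery in the real JL data may therefore be lower. Of 20873 genes, 775 (3.71%) had an unadjusted p below 0.05. DESeq2 called 44 genes, limma-trend on FPKM 0 and voom with library quality weights 1. The libraries of the 2 groups did not overlap in 5.19% of genes, against 10% by chance. The genes that moved in SCS showed small shifts here: the 854 raised in SCS had a median log2 fold change of 2.62 there and 0.23 in JL, and the 1130 lowered in SCS had medians of -2.27 and -0.11. Of these sets 68.1% and 62.8% had the same sign in JL as in SCS, against 53.3% of all genes. The JL shift of the sets had a p of 6.10e-06 and 8.00e-04 by camera, 0.347 and 0.458 with an estimated correlation, and 0.449 and 0.531 by fry. In the interaction 39 and 68 of their genes were called, but that comparison contains the SCS change by which the sets were picked. Across all tested genes, which are not independent, the log2 fold changes of the 2 cultivars had a Pearson r of 0.220 and a Spearman rho of 0.123.

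Dehydrin DHN1 (LOC8077913) stood at 6.59 ± 8.50 in JL control and 69.5 ± 116 CPM in JL drought, and LEA protein 1 (LOC8055903) at 1.15 ± 0.784 and 0.270 ± 0.243 CPM. The drought mean of DHN1 came mostly from 1 library, as its SD above the mean shows. Of the 22 LEA and dehydrin genes none was called, 15 had a positive log2 fold change and the median was 1.18, or 1.01 with genes at 0 set to their bound (adjusted p = 0.0945 by camera and 0.997 by fry). Photosystem genes had a median of 0.066 in JL, which turned negative under upper-quartile scaling (adjusted p = 0.250 by camera and 0.997 by fry). The P5C synthase genes LOC110430201 and LOC110433516 stood at 24.2 ± 17.1 and 169 ± 112 in control and 11.1 ± 4.65 and 108 ± 85.7 CPM in drought. Ornithine aminotransferase (LOC8062211) stood at 34.6 ± 10.7 and 32.7 ± 7.70 CPM, and the proline transporter genes LOC8078705 and LOC8081574 at 153 ± 35.3 and 144 ± 14.2 in control and 99.97 ± 48.8 and 122 ± 41.3 CPM in drought. None of these had an adjusted p below 1, and the proline list had one of 0.454 by camera and 0.997 by fry. Genes of dhurrin metabolism ranged widely among the JL drought libraries. The tyrosine N-monooxygenase gene LOC8061413, of the first step of synthesis (chromosome 1, 1144020 to 1146258), stood at 20.1 ± 20.5 and 261 ± 444 CPM, the latter from libraries of 7.74, 775 and 1.83 CPM. The glucosyltransferase gene LOC8060874 stood at 77.5 ± 12.4 and 188 ± 279 CPM, and the lyase gene LOC110435085 at 173 ± 75.8 and 460 ± 497 CPM. In control LOC8060874 stood far higher in JL than in SCS, though not called, so its drought changes start from unlike levels. Without JL drought 2 the log2 fold change of LOC8061413 turned from 3.71 to -2.07 and that of LOC8060874 from 1.28 to -1.52. The oxime monooxygenase genes LOC8060873 and LOC8060872 stood at 64.5 ± 22.6 and 27.2 ± 7.13 in control and 218 ± 197 and 125 ± 118 CPM in drought. The dhurrin list had an adjusted p of 0.890 by camera and 0.997 by fry, and no member was called over all genes or adjusted over the list alone.

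By camera 3 lists were called in JL, each at an adjusted p of 0.0147: ethylene synthesis and response genes stood higher than other genes (median 0.37; adjusted p = 0.0179 without the 5 methylene products), and heat shock proteins and cytosolic ribosomal proteins lower (-0.14 and -0.15). With an estimated correlation their adjusted p was 0.785, 0.785 and 0.966, fry gave 0.997 for each, no member of the 3 lists was called, and other splits of the 6 JL libraries gave 5 to 14 lists. The ethylene call was lost without JL control 1, JL drought 1 or JL drought 2 (adjusted p up to 0.25), the heat shock call without JL control 3 or JL drought 1 (up to 0.453) and the ribosomal call without JL control 3 or JL drought 2 (up to 0.711). Camera called 6, 5 and 6 lists without JL control 1, 2 and 3 and 7, 6 and 10 without JL drought 1, 2 and 3. The number of genes called reached 1 without JL control 1 and 2 without JL drought 1.

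**Figure D3:**
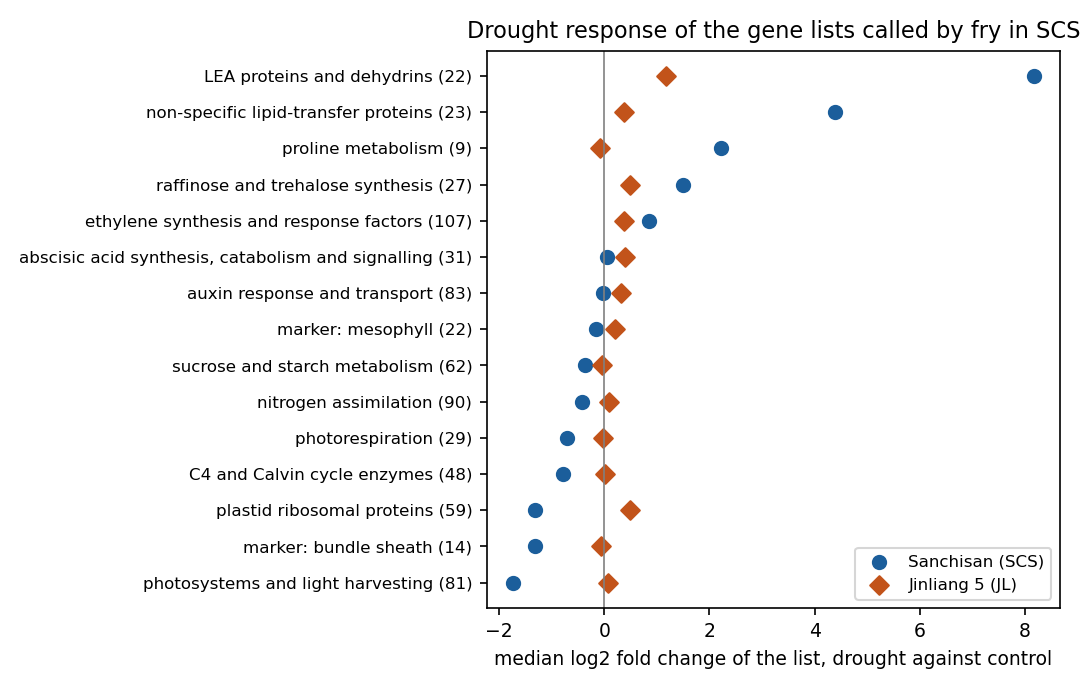
Median log2 fold change, drought against control, of the 15 gene lists that fry, but not camera with an estimated correlation, called in SCS (number of tested genes in brackets; the ethylene list holds 5 methylene products), with circles for SCS, diamonds for JL and a line at 0. Medians run from -1.74 (photosystems) to 8.17 (LEA proteins) in SCS, where the auxin list changes sign under RLE scaling, and fry called none of the lists in JL, where the medians of the photosystem and the C4 and Calvin cycle lists change sign under upper-quartile scaling.

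The interaction asks whether the change under drought differed between the cultivars. It is the JL change minus the SCS change, and 107 genes were called, 68 with a higher and 39 with a lower change in JL. These directions were 61 and 115 with limma-trend on FPKM with no filter, and 7 and 1 without SCS control 3. The ricin B-like lectin gene LOC8084563, of a family known in rice as responsive to abscisic acid and salt (chromosome 1, 67327300 to 67329184), went from 7.88 ± 2.52 to 1985 ± 1193 CPM in SCS and from 26.1 ± 6.62 to 7.15 ± 4.32 CPM in JL (adjusted p = 0.00602). RADIALIS-like 3 (LOC8064723, chromosome 9, 58029467 to 58030577), of a small family of MYB-related factors, went from 104 ± 48.5 to 0.539 ± 0.320 CPM in SCS and from 164 ± 19.8 to 128 ± 63.6 CPM in JL (adjusted p = 0.00977). LOC110433327 of the NRT1/PTR family, at 2 counts in SCS drought, stood at 56.7 ± 20.9 and 30.6 ± 20.2 CPM in JL (adjusted p = 0.00998). These 3 genes kept the call without any 1 library. LOC8084563 and LOC8064723 also kept it in all 26 alternative fits. LOC110433327 lost it with limma-trend on FPKM at a pseudocount of 1, with and without the filter (adjusted p up to 0.13). Its log2 difference ranged from 2.54 to 9.09 over the alternatives.

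Named genes with a lower change in JL included LOC8065192, LOC8055903 and the ABA-inducible LEA gene LOC8059830, which went from 2.37 ± 2.01 to 1663 ± 832 CPM in SCS and from 0.496 ± 0.435 to 0.104 ± 0.180 CPM in JL. In JL drought LOC8065192 stood at 0.533 ± 0.593 CPM and LOC8055903 at 0.270 ± 0.243 CPM. The lipid-transfer gene LOC8061116, a glycine-rich cell wall gene (LOC8077859) and an NADP-malic enzyme gene whose product is not named as plastid (LOC8075558) reached 105 ± 45.9, 121 ± 83.1 and 703 ± 517 CPM in SCS drought against 1.09 ± 1.07, 4.10 ± 2.98 and 0.499 ± 0.610 CPM in JL drought. Ornithine aminotransferase (LOC8062211) and P5C synthase 1 (LOC110430201) were called (adjusted p = 0.0392 and 0.0413), as were the small heat shock gene LOC8073756 and the HSP70 gene LOC8085292 (0.0292 and 0.0456). Of 12 fits without 1 library, these genes kept the call in 2, 1, 3 and 2. Proline transporter 1 (LOC8078705), of the same list as LOC8062211 and LOC110430201, was called in the opposite direction, with a higher change in JL (5.17, adjusted p = 0.0371), and lost the call in 10 of 12 fits without 1 library. It falls outside the rule, which takes list members that move with their list, and was named after its value was seen. In JL drought the oxidoreductase gene LOC8083891 stood at 98.04 ± 82.3 CPM, SAG39 (LOC8086230) at 454 ± 452, nepenthesin-1 (LOC8074284) at 142 ± 97.5, an esterase gene (LOC110431387) at 246 ± 127 and the plastid protein gene LOC8074089 at 1547 ± 137, against 0.0675 ± 0.117, 0.486 ± 0.349, 0.450 ± 0.517, 1.05 ± 0.947 and 5.38 ± 3.79 in SCS drought. The plastid-encoded photosystem gene psbC went from 11.4 ± 1.54 to 4.85 ± 0.552 CPM in SCS and from 11 ± 2.14 to 19.9 ± 1.67 CPM in JL (adjusted p = 0.0392). It kept the call in 10 of 25 alternative fits, among them 2 of the 12 without 1 library. All organelle genes together took only 0.0246% (SCS drought 3) to 0.0584% (SCS control 2) of a library's counts. Whether such a small share follows the level of plastid transcripts in the leaf was not tested. The receptor genes LOC8084167, LOC8073249 and LOC8066296 stood at 169 ± 54.7, 11.4 ± 5.65 and 7.57 ± 2.46 in JL drought, against 6.68 ± 3.23, 0.888 ± 0.394 and 0.208 ± 0.160 in SCS drought.

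By camera 11 lists differed, and none of the 47 did with an estimated correlation (adjusted p of 0.297 or more). Fry called the LEA list (adjusted p = 0.00457), the lipid-transfer list (0.0198) and the auxin list (0.0203). Members with a higher and a lower change in JL over all genes, with those adjusted over the list alone in brackets, were 0 and 1 of 22 for LEA proteins (1 and 8), 0 and 1 of 23 for lipid-transfer proteins (0 and 10), 1 and 2 of 9 for proline (1 and 5) and 0 and 2 of 163 for heat shock proteins (0 and 5). They were 1 and 0 of 81 for photosystems (30 and 0), 0 and 1 of 48 for the C4 and Calvin cycle (17 and 3) and 4 and 0 of 558 for receptors (6 and 0). No member passed over all genes in the raffinose (0 and 3), chlorophyll synthesis (1 and 0), plastid ribosomal (15 and 0) and cytosolic ribosomal lists (0 and 0). The count of 107 changed without 1 library: it was 9, 15 and 8 without SCS control 1, 2 and 3, 16, 36 and 424 without SCS drought 1, 2 and 3, 23, 17 and 8 without JL control 1, 2 and 3, and 31, 224 and 10 without JL drought 1, 2 and 3. Here too, lost power from fewer libraries was not separated from dependence on a given library. Of the 22 named genes 3 kept the call in all 12 of these fits, with 19, 18 and 19 calls lost without SCS control 1, 2 and 3, 15 and 15 without SCS drought 1 and 2, 16, 16 and 18 without JL control 1, 2 and 3 and 17, 2 and 18 without JL drought 1, 2 and 3. The 11 lists became 7 without SCS drought 3. Among 100 regroupings of the cultivar labels, 10 others called as many genes.

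Between the cultivars in control, 5 genes were called, 2 higher and 3 lower in JL. A locus the authors assembled without a reference gene, described as a succinate dehydrogenase subunit (chromosome 10, 2512685 to 2515072), stood at 0.269 ± 0.118 in SCS and 9.01 ± 1.91 CPM in JL (adjusted p = 0.019), and the plastid thioredoxin-like gene LOC8080535 (chromosome 1, 76910928 to 76912785) at 3.62 ± 0.461 and 20.2 ± 5.24 CPM (0.0473). A protease Do-like gene (LOC8057143, chromosome 5, 11579102 to 11584619) stood at 8.90 ± 1.33 and 0.619 ± 0.3 CPM (0.034). The helicase gene PIF1 (LOC8155712, chromosome 2, 56384639 to 56386816) had no count in JL control against 10.5 ± 4.51 CPM in SCS, at least 129-fold lower (0.034). Its neighbour LOC8055583 (chromosome 2, 56381500 to 56383934), with no product description, had 1 count in JL control against 11.6 ± 4.58 CPM in SCS, a ratio of 430 (76.997 to 17022) (0.034). LOC8055583, LOC8057143 and the assembled locus fall outside the rule for named genes and were named after their values were seen. Of 20873 genes, 3008 had an unadjusted p below 0.05 and 27.6% had no overlap of libraries (10% by chance), and DESeq2 called 700. None of the 5 calls held in every fit: no gene was called without SCS control 1, 2 or 3 or JL control 2 or 3, and 6 were called without JL control 1, of which 2 were among the 5. By camera 13 lists differed in control, 10 higher and 3 lower in JL, but none by fry or with an estimated correlation. Medians were 0.96 for photosystems, 1.25 for chlorophyll synthesis and -0.62 for cytosolic ribosomal proteins, with no member called over all genes, and 0.012 for LEA proteins, which became 0 under upper-quartile scaling or with genes at 0 set to their bound. The dhurrin list had the highest median of all lists in control, 2.50, and one of 2.34 in drought. The list tests in control were not among those set in advance.

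Under drought, where the leaves of SCS had changed, 3916 genes were called between the cultivars, 2341 higher and 1575 lower in JL. Upper-quartile scaling gave 1984 higher and 1918 lower. The compared libraries alone gave 1247 calls, 848 higher and 399 lower, but that fit has fewer libraries. The median SD within a group was 0.58 in SCS drought and 0.66 in JL drought, against 0.41 and 0.43 in control. The spread shared by all groups may therefore be too small for the drought libraries. This comparison shares the SCS drought libraries with that of drought in SCS. By fry the photosystem and chlorophyll synthesis lists stood higher in JL, and the LEA and cytosolic ribosomal lists lower, while camera with an estimated correlation called none. Markers of leaf cell types stood higher in JL as well: of 14 bundle sheath markers 8 were higher and 2 lower, and of 22 mesophyll markers 9 and 1. Their medians were 2.12 and 1.13, against 0.60 and 0.50 in control, with an adjusted p in drought of 0.00310 and 0.00102 by fry and 0.495 for both with an estimated correlation. Libraries did not overlap in 32.8% of genes, against 10% by chance. Expansins loosen the cell wall. In JL drought LOC8085403, LOC8058097 and LOC8055661, all at 0 counts in SCS drought, stood at 36.9 ± 52.5, 14.5 ± 22.99 and 12.2 ± 14.99 CPM, at least 691-fold, 269-fold and 231-fold higher (adjusted p = 0.00738, 0.0344 and 0.0171). LOC8058096 stood at 161 ± 256 CPM against 0.154 ± 0.220, and LOC8077003, with 1 count in SCS drought, at 23.9 ± 31.9 CPM, a ratio of 1357 (243 to 53663). The spread among the JL libraries exceeded the mean for each of these expansins. Without JL drought 2 the values of LOC8085403, LOC8058097, LOC8055661 and LOC8077003 became 131-fold, 23.5-fold, 71.4-fold and 346-fold, and without JL drought 3 that of LOC8058097 became 414-fold. The log2 fold change of LOC8058096 went from 9.99 to 6.44 without JL drought 2. The fatty acyl-CoA reductase gene LOC8057991, of wax alcohol synthesis, stood at 245 ± 400 CPM in JL and 0.0654 ± 0.0782 in SCS (adjusted p = 0.0132), and its log2 fold change went from 11.70 to 7.54 without JL drought 2. LOC110433327 was higher in JL, with a ratio of 946 (261 to 7823), as were LOC8083891 and SAG39 (LOC8086230), with log2 fold changes of 10.37 and 9.85, and the aldo-keto reductase gene LOC8072091, with a ratio of 542 (185 to 2632). The ratio of LOC110433327 became 569 without JL drought 3, and that of LOC8072091 192 and 835 without JL drought 2 and 3. LOC8058097 and LOC8072091 lost their calls without SCS drought 1, 2 or 3 or JL drought 2 (adjusted p up to 0.0895 and 0.103), and LOC8055661, LOC8058096 and LOC8057991 without SCS drought 1 (0.0532, 0.0602 and 0.0583).

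Several transcripts of SCS drought had no count in JL drought. The LEA genes LOC110430243 and LOC8073244 were at least 24383-fold and 1260-fold lower in JL, and the plastid pore gene LOC110434017 at least 3228-fold. A vicilin-like storage protein gene (LOC8081885) stood at 80.1 ± 64.7 CPM in SCS, a small heat shock gene (LOC8076920) at 61.1 ± 49.9 and the oil body gene LOC8069824 at 39.4 ± 45.7, at least 955-fold, 729-fold and 465-fold lower in JL. Malate synthase (LOC8073689), of the glyoxylate cycle by which seedlings use stored oil, was at least 508-fold lower (adjusted p = 0.0471), and an F-box gene (LOC8060956) and laccase-5 (LOC8060081) at least 498-fold and 487-fold. Malate synthase lost its call without SCS drought 1 or 3 or any of the 3 JL drought libraries (adjusted p up to 0.114), and laccase-5 without SCS drought 1 or JL drought 3 (up to 0.0744). Without SCS drought 1 the bounds of LOC110430243, LOC8073244, LOC110434017, LOC8073689, LOC8060956 and LOC8069824 became 15962-fold, 711-fold, 2104-fold, 197-fold, 274-fold and 167-fold. That of laccase-5 became 173-fold without SCS drought 2 and 753-fold without SCS drought 3, where those of LOC8081885 and LOC8076920 became 1485-fold and 1138-fold. The ABA-inducible LEA gene LOC8059830 was lower by a log2 fold change of -13.86 (SE 1.61, adjusted p = 0.00139). By list, 61 of 81 photosystem genes were higher in JL and 0 lower (65 and 0 adjusted over the list alone), 16 and 0 of 29 chlorophyll synthesis genes (19 and 1). The counts were 0 and 14 of 22 LEA genes (1 and 16) and 0 and 95 of 204 cytosolic ribosomal genes (0 and 134). Their adjusted p was 0.00102, 0.0204, 2.65e-04 and 0.0119 by fry, and 0.495, 0.518, 0.495 and 0.495 by camera with an estimated correlation. Their medians were 2.95, 1.99, -5.52 and -0.95, against 0.96, 1.25 and -0.62 in control for the first, second and last. Of 163 heat shock genes 11 were higher and 29 lower in JL (11 and 32 adjusted over the list alone; median -0.38; adjusted p = 0.0129 by fry and 0.495 with an estimated correlation). The expansin list, with 10 and 1 of 33 genes (12 and 1), was called by camera (adjusted p = 0.0363) but not by fry (0.0714) or with an estimated correlation (0.620). Its median was 2.11, against 1.71 in control, or 1.36 with genes at 0 set to their bound. The list tests of this comparison were not among those set in advance and were not run under the alternatives. Without SCS drought 1 the 3916 calls became 1811. Of the 20 named genes 13 kept the call without any 1 library, with 7 lost without SCS drought 1, 2 without SCS drought 2, 3 without SCS drought 3 and 1, 3 and 2 without JL drought 1, 2 and 3.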

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

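The tests of whether leaving out 1 library raises the JL count and those on genes nearly absent in JL were chosen after the results were seen, as were the largest move of a JL pair, the fry counts over other splits and the breakdown of regroupings by their drought libraries. The expected values for the other splits and regroupings, the spread in JL, exchanged libraries and the shared direction were written before their results were seen.

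The interaction compares the drought change of the 2 cultivars, and each result here was taken up because that test found a difference. It called 107 genes. The log2 difference, JL change minus SCS change, was 9.42 for LOC8083891, 8.69 for LOC110433327, 7.998 for LOC8086230, 7.97 for LOC8074284, 7.23 for LOC8064723, 7.14 for LOC110431387 and 6.60 for LOC8074089. It was -15.42 for LOC8065192, -11.64 for LOC8059830, -10.62 for LOC8077859, -10.22 for LOC8055903, -10.15 for LOC8061116, -10.10 for LOC8075558 and -9.84 for LOC8084563. Members of called lists had differences of -2.30 (LOC8062211), -5.17 (LOC110430201), -4.64 (LOC8073756), -4.68 (LOC8085292), 5.17 (LOC8078705), 2.08 (psbC), 5.35 (LOC8084167), 4.94 (LOC8066296) and 4.15 (LOC8073249). The 11 lists that camera called had median differences of -4.13 (LEA proteins), -3.65 (lipid-transfer proteins), -2.30 (proline), -0.73 (raffinose and trehalose), -0.39 (heat shock proteins), -0.32 (cytosolic ribosomal proteins), 1.98 (photosystems), 2.08 (plastid ribosomal proteins), 1.06 (C4 and Calvin cycle), 1.06 (chlorophyll synthesis) and 0.97 (receptors). The lists' adjusted p with an estimated correlation ran from 0.297 to 0.815. Values of genes with no count in a group, such as LOC8065192, and medians of lists that hold such genes depend on the prior count. Without 1 library the calls of the proline, raffinose, C4, chlorophyll and cytosolic ribosomal lists could be lost: proline without SCS control 2, SCS drought 1, SCS drought 3 or JL control 1 (adjusted p up to 0.179), raffinose without SCS drought 3 or JL drought 3 (up to 0.165), C4 without SCS drought 3 or JL drought 2 (up to 0.078), chlorophyll synthesis without replicate 3 of SCS control, SCS drought or JL control or without JL drought 2 (up to 0.487) and cytosolic ribosomal proteins without JL control 3 (up to 0.071).

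In 100 regroupings of the cultivar labels within treatments, the real one included, 11 called 107 genes or more (highest other 4323) and 51 called 11 lists or more by camera (highest other 20), so chance is not excluded for either count. Of the 10 other regroupings with as many genes, 9 kept the drought libraries of each cultivar together, and among the 85 that mixed them 1 called as many (816), which would go with a structure of the samples in which the drought libraries of a cultivar lie together. Regroupings that keep these libraries together also hold the cultivar difference in drought. The share of 11 in 100 therefore cannot decide on chance for the gene count. For drought in SCS 1 of 10 splits, the real one, gave 1984 genes (highest other 0) and 6 of 10 gave 10 lists or more (highest other 17). For JL all 10 splits gave 0 genes or more (highest other 1) and 10 gave 3 lists or more (highest other 14). For the cultivars in control 1 of 10 gave 5 genes (highest other 0) and in drought 1 of 10 gave 3916 (highest other 33). With 10 splits no share can fall under 0.05. The other splits mix the 2 groups, so a true difference between the groups widens the spread and lowers the counts of genes and of fry lists. Fry gave 15 lists for the real SCS split and 0 for the 9 others, 0 and at most 2 for JL, and for the interaction 3 lists, which 11 other regroupings matched.

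Drought in SCS gave 1984 calls and drought in JL 0. If a larger spread in JL hid a response of the same size, the 500 genes with the smallest p for drought in 4 SCS libraries would move in JL by at least 50% of their move in the left-out SCS pair. The JL libraries entered the estimate of spread in that fit, so genes that vary little in JL could be favoured. Over the 9 pairs the highest value was 7.75%, with medians of 1.79 to 3.34 in SCS and 0.10 to 0.18 in JL. This argues against a hidden response of the same size in these genes. Libraries exchanged between JL groups would let another split call many genes, and the highest was 1. A single deviating JL library stays open: without 1 library the highest count was 2, but 2038 of 21875 genes had an unadjusted p below 0.05 without JL drought 3, where camera called 10 lists. The largest median move of the 500 genes in a JL pair was 0.563, so in these genes such a library could hide only a smaller response than that of SCS. The genes were picked in SCS, and a JL response in other genes was not examined. A difference between the cultivars in their response, or in the stress that their leaves had reached when sampled, may underlie the contrast, and no measurement here tells these apart.

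Libraries of 1 group differed along a direction that was similar in both cultivars. Its axes, found in the 6 SCS and in the 6 JL libraries separately, correlated across genes with an r of 0.548, the sign of each set by the axis of all 12. No r expected for unrelated libraries was computed, and genes that vary together could give such a value. Unrelated single libraries therefore stay open. The loading of the direction had a Spearman rho of 0.0873 with gene length, against a length effect such as degraded RNA would give. Library size stays open: over the 12 libraries the score had an r of -0.227 and a rho of -0.273 with the deviation of the total (permutation p = 0.573 for r; r = -0.155 without the 2 libraries farthest from the median), and 3 libraries a group are too few to decide. WRKY and NAC factors and glutathione S-transferases had median gene correlations of -0.672, -0.658 and -0.627 with it, and chlorophyll synthesis 0.684. No biological explanation was tested, since the labels give no growth stage or sampling time.

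The neighbouring genes LOC8055583 and LOC8155712, at 56381500 to 56386816 on chromosome 2, had a mean of 228 and 212 counts in the SCS libraries and 1 and 0 counts over the 6 JL libraries. They are the only genes with 10 or more counts in each SCS library and 3 or fewer over JL, a limit eased from 0 after 1 gene had met it, and 2 genes that do not neighbour each other show the reverse. Chance placement stays open: the 1 adjacent pair had prompted the test, and the eased limit let in its second gene. The median mean count of 220 per SCS library argues against expression near the detection floor. A stretch that is deleted or diverged in JL may account for both genes. That 2 of 2 have such a neighbour lends it no weight, since this pair prompted the test. Reads that no longer align and shared silencing would give the same counts and cannot be told apart from such a stretch without reads.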

How the results depend on the processing

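The fits without the drought libraries numbered 2, with 1 surrogate variable and with voom quality weights, camera on the counts and the changed list members were chosen after seeing the data. For drought in SCS the 1984 calls became 4065 with DESeq2, 1042 with glmTreat against a fold of 1.5 and 8608 with voom weights, and 533 to 2619 without 1 library. For JL the 0 calls became 44 with DESeq2 and 1 with voom weights, and 0 to 2 without 1 library. The interaction count of 107 became 1357 with DESeq2, 61 with glmTreat, 250 and 242 with limma-trend on FPKM at pseudocounts of 1 and 0.1 (106 higher and 144 lower at the former, against 68 and 39), 176 with no FPKM filter, 187 without the drought libraries numbered 2, 470 with a surrogate variable, 1912 with voom weights, and 8 to 424 without 1 library. In control the 5 calls became 700 with DESeq2, 11 with the compared libraries alone, 10, 10 and 27 with the FPKM fits, 3 without unannotated loci and organelle genes, 0 without the drought libraries numbered 2, 9937 with voom weights and 0 to 6 without 1 library. In drought the 3916 calls became 6055 with DESeq2, 1247 with the compared libraries alone, 2307 with glmTreat and 1811 to 3507 without 1 library. DESeq2's larger counts stand beside its false calls and its higher recovery on simulated data, and fewer calls follow by construction from glmTreat's fold. The cause of the other changes was not tested. Voom gave SCS control 1 a weight of 7.99 and JL control 2 one of 4.85. The other control libraries had 0.574 to 1.11. In SCS drought the weights of libraries 1, 2 and 3 were 2.93, 0.285 and 0.455. The voom counts thus lean on 1 library in each of these groups. Upper-quartile scaling moved the median log2 fold change of all genes in drought by -0.13. Replicate numbers did not pair the libraries: 5 of 18 same-number pairs had a correlation above 0.1 and 3 of 12 libraries correlated best with their own number. With the number as a replicate block 1399, 0, 17, 0 and 2748 genes were called for drought in SCS, drought in JL, the interaction, control and drought, and 10, 3 and 10 lists for the first 3. Camera's 10, 3 and 11 lists became 0, 0 and 0 with an estimated correlation. For SCS fry gave 15 and camera on the counts 16, and 7 to 12 were called without 1 library. For JL fry gave 0, camera on the counts 8, the fit without the drought libraries numbered 2 gave 6, and 5 to 10 were called without 1 library. For the interaction fry gave 3, and 7 to 14 were called without 1 library. Of the alternative values of named genes in SCS 1160 of 1259 kept direction and side of the threshold, 79 lost the call, 11 gained it and 9 changed sign. For JL 195 of 208 kept both and 13 changed sign, for the interaction 360 of 571 with 211 calls lost, in control 58 of 104 with 46 lost and in drought 371 of 417 with 46 lost. Over every gene of the rule, named or not, 11 of 1301 values changed sign in SCS and 39 of 374 in JL. The changes of sign lay with genes not called: LOC8081574 in SCS (0.08) took -0.0095 with the replicate block, -0.053, -0.060 and -0.053 with the FPKM fits and -0.19 to 0.46 without 1 library, LOC8060873 -0.074 with the surrogate variable, LOC8072535 -0.95 to 0.021 without 1 library and LOC8060872 -12.98 to 0.65 without 1 library. In JL LOC110433516 took -1.42 to 0.049 without 1 library, LOC8062211 0.077 with voom weights and -0.29 to 0.19 without 1 library, LOC8060874 -0.10, -0.13 and -0.10 with the FPKM fits, -1.52 without the libraries numbered 2, -0.67 with voom weights and -1.52 to 1.81 without 1 library, and LOC8061413 -2.07, -0.13 and -2.07 to 4.97 in the last 3. Libraries held 15.04 M counts or more, and the effect of depth was not tested. For genes with 0 counts in a group, the floor of 3 counts over the group bounds the fold.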

Other observations

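The lists and genes of this part were picked for the text after their values were seen, while the lists themselves and their tests in SCS had been set beforehand. In SCS drought, genes around the hormone abscisic acid moved in both directions. Of 31 tested, 5 rose and 2 fell (7 and 2 adjusted over the list alone), with an adjusted p of 0.0281 by fry, 0.0871 by camera and 0.445 with an estimated correlation. The synthesis gene LOC8062208 (9-cis-epoxycarotenoid dioxygenase, the step that commits carotenoids to abscisic acid) rose from 1.79 ± 0.388 to 68.95 ± 25.5 CPM in SCS (log2 fold change 5.26) and stood at 5.74 ± 4.001 and 87.9 ± 113 CPM in JL, where it was not called. Its interaction was -1.34 (adjusted p = 0.694). LOC8073163 (abscisic acid 8'-hydroxylase, which breaks the hormone down) rose from 0.852 ± 0.251 to 18.1 ± 6.47 CPM, the stress and ripening gene LOC110429605 from 63.8 ± 13.2 to 2088 ± 1309 CPM and the kinase gene SAPK3 (LOC110431683), of the family that carries the signal, from 4.77 ± 1.67 to 85.8 ± 14.6 CPM. The receptor genes LOC8065946 and LOC8078346, both named PYL8, went apart: the former rose from 18.1 ± 2.70 to 42.5 ± 6.79 CPM and the latter fell from 104 ± 32.8 to 41.3 ± 7.58 CPM. The kinase gene SAPK5 (LOC8076517) fell from 83.2 ± 31.6 to 27.9 ± 6.11 CPM. Of 75 protein phosphatase 2C genes, a family that includes repressors of the abscisic acid signal, 11 rose and 3 fell (14 and 7 adjusted over the list alone), and the list was not called (adjusted p = 0.540 by camera and 0.667 by fry). Its median was -0.085 and its mean 0.57. LOC8084948 rose from 3.95 ± 0.97 to 581 ± 224 CPM, LOC110430337 from 1.20 ± 0.549 to 195 ± 78.5 CPM and LOC8078159 from 35.2 ± 7.10 to 85.7 ± 12.3 CPM, while LOC110433972 fell from 29.1 ± 11.3 to 4.27 ± 1.79 CPM and LOC8075001 from 314 ± 121 to 82.8 ± 31.6 CPM.

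Of 163 heat shock protein and chaperone genes 18 rose and 3 fell in SCS drought (20 and 4 adjusted over the list alone; adjusted p = 0.0655 by camera and 0.192 by fry). The HSP70 genes LOC8057776 and LOC8085292 rose from 144 ± 16.6 and 9.05 ± 2.56 to 1570 ± 484 and 221 ± 133 CPM, the small heat shock gene LOC8073756 from 0.590 ± 0.187 to 14.6 ± 6.57 CPM, and the plastid HSP70 gene LOC8061221 fell from 301 ± 48.1 to 152 ± 25.1 CPM. Another small heat shock gene, LOC8073344, fell from 180 ± 20.4 to 34.9 ± 26.1 CPM. Of 51 genes on the list of flower and seed markers 6 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.276 by camera and 0.192 by fry). Oleosin 1 (LOC8059544), a coat protein of oil bodies, rose from 1.86 ± 0.916 to 117 ± 82.7 CPM, the MADS-box gene LOC110431897 from 5.97 ± 0.0913 to 93.7 ± 73.1 CPM and LOC8078486, named for a pollen extensin, from 29.96 ± 2.46 to 62.7 ± 14.5 CPM. The kinase gene LOC8069382 fell from 67.5 ± 13.8 to 22.5 ± 7.07 CPM. Aquaporins pass water through membranes. Of 24 genes 3 rose and 0 fell (6 and 3 adjusted over the list alone; adjusted p = 0.643 by camera and 0.474 by fry; median -0.32, mean 0.19): PIP1-2 (LOC8076062) went from 222 ± 102 to 2034 ± 1242 CPM, PIP2-1 (LOC8059750) from 225 ± 40.2 to 711 ± 108 CPM and TIP2-2 (LOC8085362) from 20.3 ± 15.8 to 150 ± 65.7 CPM. Without SCS control 1 calls were lost for LOC8062208, LOC8065946, LOC8078346, LOC8078159, LOC8084948, LOC8061221, LOC110431897, LOC8078486, LOC8059544, LOC8069382, LOC8076062, LOC8059750 and LOC8085362. Without SCS control 2 calls were lost for LOC8062208, LOC8065946, LOC8084948, LOC8061221, LOC8059544, LOC8069382, LOC8076062, LOC8059750 and LOC8085362. Without SCS control 3 calls were lost for LOC8062208, LOC8065946, LOC8076517, LOC8078346, LOC8084948, LOC110433972, LOC8075001, LOC8057776, LOC8073344, LOC8061221, LOC110431897, LOC8078486, LOC8059544, LOC8069382, LOC8059750 and LOC8085362. Without SCS drought 1 calls were lost for LOC8062208, LOC8065946, LOC8078346, LOC8078159, LOC110433972, LOC8075001, LOC8073344, LOC8061221, LOC8078486, LOC8059544, LOC8069382, LOC8076062, LOC8059750 and LOC8085362. Without SCS drought 2 calls were lost for LOC8062208, LOC8065946, LOC8076517, LOC8078346, LOC8059750 and LOC8085362. Without SCS drought 3 calls were lost for LOC8061221. Of the 24 genes named in this part 6 kept the call without any 1 library: LOC110429605, LOC110431683, LOC8073163, LOC110430337, LOC8073756 and LOC8085292.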
